A study of Homo sapiens with 12 samples.

How the data were processed

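Poly(A) RNA of OCI-AML3 cells, an established human acute myeloid leukaemia line, was sequenced as paired ends after 24 h of treatment. The 12 libraries form 4 groups of 3: DMSO, the solvent control; venetoclax (ABT199 in the labels), an inhibitor of the survival protein BCL2; an ERK inhibitor (ERKi in the labels); and the combination of both drugs. Groups and replicate numbers were taken from the labels. Nothing in the labels states that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

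The deposited table holds raw read counts for 54628 gene symbols in the 12 libraries. Per the submitters' processing notes, HISAT2, HTSeq and DESeq2 were used with the hg38 build. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes may be shared. The values were whole numbers with a different total in each library, and 0 rows named no gene. Of the symbols, 51616 matched a RefSeq gene of GRCh38, from which gene positions were taken.

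Library totals ran from 19199296 to 21275065 counts. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 15173, and libraries were scaled by TMM factors. This scaling takes most genes as unchanged, so rises and falls are relative to it and a shift of all genes alike would not show. One model with 1 coefficient per group was fitted to all 12 libraries with 8 residual degrees of freedom, and each comparison was tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.073. Log2 fold changes used a prior count of 0.125, and each standard error is the fold change divided by the square root of F. CPM values are the deposited counts divided by the scaled library size, times 1e+06. The comparisons were each treatment against DMSO, the combination against each single drug, and the departure of the combination from the sum of both single effects on the log2 scale, here called the interaction.

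There were 31 gene lists, tested by camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. In the latter setting camera also rests on the 8 residual degrees of freedom instead of the number of genes. Its p can therefore be much larger even where the estimated correlation is no higher than the preset. Camera asks whether members moved more than other genes, and fry, run as well, whether they moved at all. Lists, comparisons, tests and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the protein-coding genes with the largest rises and falls (8 each against DMSO, 5 each otherwise) among called genes with a mean CPM of at least 5 and, between 2 groups, no overlap of the groups. It added up to 4 called members of each list by adjusted p and 21 fixed genes of ERK signalling, mitochondrial fission and fusion and the BCL2 family. Some genes that met the rule are not reported here. Library shares were compared by exact permutation tests, for which 3 against 3 allow no p below 0.1.

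The pipeline was tested on simulated counts with known changes. For venetoclax against DMSO, with 14363 genes tested, it recovered 82.1% of 1.5-fold, 89.6% of 2-fold and 100% of 4-fold changes, with 10 false calls. For the interaction, with 14333 genes tested, the shares were 55.2%, 85.1% and 93.9%, with 9 false calls. All simulated groups had the DMSO means, apart from 66 or 67 genes per fold that were changed in a single group. No broad effect of ERKi was simulated, so these shares do not cover comparisons in which most genes changed. Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of CPM 1 in 3 libraries, the replicate number as a block, only the libraries compared, and each library left out in turn. After the data were seen, scaling without mitochondrial and non-polyadenylated RNAs, counts without genes of swinging counts, and list counts without DMSO replicate 1 were added. Figures were drawn with matplotlib 3.10.9.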

Results

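The transcriptomes of OCI-AML3 leukaemia cells were compared after 24 h with DMSO, venetoclax, an ERK inhibitor (ERKi) or both drugs, with 3 libraries per group and 19199296 to 21275065 counts per library. The series asks how blocking ERK signalling overcomes venetoclax resistance, with mitochondrial fission by Drp1 (encoded by DNM1L) as the proposed link. RNA levels, as given here, measure neither the amount or activity of the Drp1 protein nor fission itself, so they do not test that link. The first principal component held 65.6% of the variance and parted the ERKi and combination libraries from the others, and the second held 13.1% and parted ERKi from the combination. DMSO replicate 1 stood apart from the other DMSO libraries: its counts differed from theirs with a chi-square per degree of freedom of 17.93 and 16.91, against 2.34 to 5.52 for the other pairs of replicates. No pair of replicates agreed within sampling noise. Counts of list members below are over all genes tested, and those adjusted over the list alone were the same unless given.

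**Figure D1:**
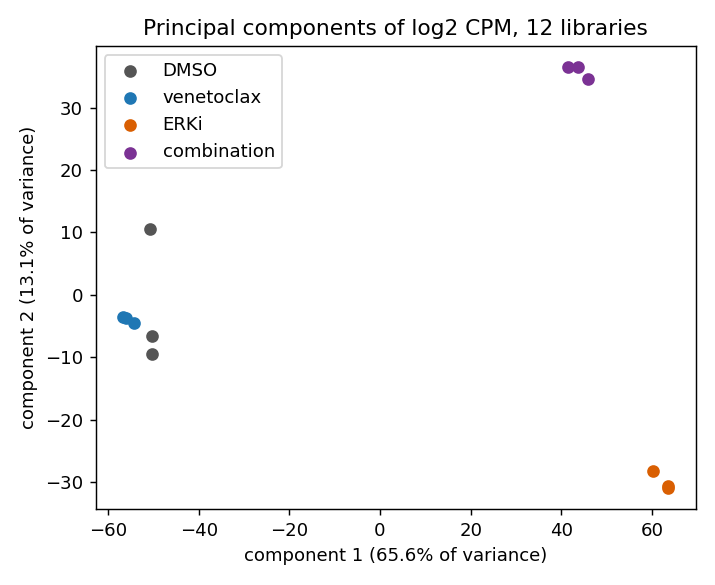
Each point is 1 of the 12 libraries, placed by the first (65.6% of variance) and second (13.1%) principal component of log2 CPM and coloured by group. The venetoclax libraries lie beside DMSO, and ERKi and the combination lie apart from both and from each other.

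Venetoclax against DMSO asked what BCL2 inhibition alone does in this line, and interferon-stimulated genes were lower. Of 29 measured interferon genes, 22 fell and none rose, with a median log2 fold change of -0.91 (28 lower when adjusted over the list alone). MX1, an antiviral GTPase on chromosome 21 (41420558 to 41459214, GRCh38), went from 47.41 ± 3.18 CPM with DMSO to 15.91 ± 0.37 (SD, n = 3), a log2 fold change of -1.57 (SE 0.082, adjusted p = 2.62e-08), lower in 3 of 3 libraries. IFI44L (-1.89), IFIT1 (-1.76), OAS3 (-1.19), OAS2 (-1.18), IFIT3 (-1.1) and XAF1 (-0.67) fell as well, on the log2 scale. The list test gave an adjusted p of 3.63e-164, and 3.63e-08 with an estimated correlation. That correlation was 0 for this list, so the larger p did not come from correlation between its genes. IRF7 (-1.22) and ISG15 (-1.2) were called too, but IRF7 lost its call without venetoclax replicate 1 (adjusted p = 0.0632) or 3 (0.0777), and ISG15 without DMSO replicate 3 (0.0882) or venetoclax replicate 2 (0.109) or 3 (0.148).

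The p53 target list was also lower with venetoclax (adjusted p = 2.01e-09, and 0.00322 with an estimated correlation), with 2 of 25 members called, 4 adjusted over the list alone and 4 without DMSO replicate 1. CDKN1A, the cell cycle inhibitor p21, fell by 0.71 on the log2 scale (SE 0.085, adjusted p = 0.00023). TNFRSF10B, a death receptor, was at -0.25 and lost its call without DMSO replicate 3 (adjusted p = 0.0691) or venetoclax replicate 1 (0.0822) or 3 (0.0777). FOS, an immediate early transcription factor, rose by 0.69 (SE 0.06, adjusted p = 7.14e-06), and BTG2 fell by 0.43, a call lost without venetoclax replicate 1 (adjusted p = 0.0573). The G2/M list was higher (adjusted p = 3.31e-07, and 0.027 with an estimated correlation) with a median of 0.09 and 1 of 34 members called, CCNB1 at 0.19. CCNB1 and TSC22D3 (0.33), and LYZ at -0.24, each lost their call without DMSO replicate 2 (adjusted p = 0.128, 0.147 and 0.0666) or 3 (0.117, 0.197 and 0.0882), and without venetoclax replicate 1 (0.26, 0.24 and 0.073), 2 (0.308, 0.201 and 0.154) or 3 (0.108, 0.165 and 0.0777). With only the libraries compared, CCNB1 (adjusted p = 0.384), TSC22D3 (0.361), LYZ (0.329), TNFRSF10B (0.221) and BTG2 (0.0963) lost their calls too. With the replicate block CCNB1 (0.088) and TSC22D3 (0.0885) did so. The lists of nuclear-encoded and mitochondrially encoded respiratory chain genes tested higher (adjusted p = 4.62e-05 and 0.00104) with 0 members called by edgeR or DESeq2 (1 of the mitochondrially encoded higher adjusted over the list alone) and 10 of 51 and 2 of 13 at an unadjusted p under 0.05, and their adjusted p was 0.457 and 0.46 with an estimated correlation.

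In all, 3 genes were higher and 58 lower with venetoclax alone. By edgeR, and also by DESeq2 and limma-voom, 0 of 17 ERK output, 13 mitochondrial fission, 12 fusion, 6 survival and 9 death genes of the BCL2 family were called. At an unadjusted p under 0.05 there were 0, 2, 2, 0 and 2. The 21 fixed genes ran from -0.14 to 0.24. Across all genes, 1382 had an unadjusted p under 0.05, and DESeq2 called 12 higher and 72 lower. The counts rested on few libraries: without DMSO replicate 1 they were 17 and 81, without DMSO replicate 3 there were 1 and 42, and without venetoclax replicate 1 or 3 there were 32 and 30 lower. Without a filter on low counts they were 74 and 168, and with only the 6 libraries compared 1 and 32.

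ERKi against DMSO asked what ERK inhibition alone does, and 69.7% of the tested genes changed, with 5232 higher and 5346 lower, of which 2085 and 1601 changed at least 2-fold. All 17 measured ERK output genes fell (adjusted p = 2.95e-07, and 0.00211 with an estimated correlation). DUSP6, the ERK phosphatase induced by the pathway itself, on chromosome 12 (89347235 to 89352501, GRCh38), went from 14.71 ± 0.64 to 2.24 ± 0.4 CPM (SD, n = 3), a log2 fold change of -2.71 (SE 0.155, adjusted p = 1.03e-10). The ETS factors ETV4 (-5.14) and ETV5 (-1.56), the early response factor EGR1 (-4.32), cyclin D1 (CCND1, -3.48), the pathway inhibitor SPRY4 (-1.11) and MYC (-0.92) fell. Of 14 immediate early genes, 10 rose, among them KLF4 (2.76), FOS (2.36) and KLF2 (1.78), and 4 fell (list adjusted p = 0.000224, and 0.0183 with an estimated correlation).

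Genes of proliferation and biosynthesis fell with ERKi. All 37 G1/S genes were lower with a median of -1.84, such as the replication licensing genes CDC6 (-2.59) and MCM4 (-1.95), as were all 34 G2/M genes with a median of -1.37, such as CCNA2 (-1.88) and CDK1 (-1.44). Ribosome biogenesis genes fell in 29 of 30 cases (30 adjusted over the list alone), including NOLC1 (-1.52) and NCL (-1.24). Of 31 targets of the stress factor ATF4, 26 fell, such as the serine synthesis enzymes PSAT1 (-3.89) and PHGDH (-3.85) and the amino acid transporter SLC7A5 (-3.42). Cholesterol synthesis genes fell in 20 of 22 cases (HMGCS1 -1.28), and unfolded protein response genes in 14 of 19 (HSPA5 -1.15, XBP1 -1.59). These lists kept an adjusted p of 0.016 or lower with an estimated correlation. Glycolysis genes were lower in 16 of 21 cases (LDHA -1.14, PGK1 -1.05) and tricarboxylic acid cycle genes in 16 of 17 (SDHB -0.91), but both had an adjusted p of 0.236 with an estimated correlation.

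Monocyte genes rose with ERKi. Of 21 measured, 14 rose and 4 fell, with S100A8 at 4.7, LYZ at 3.54, VCAN at 3.44 and CD36 at 1.68 (list adjusted p = 1.79e-13, and 0.00211 with an estimated correlation). LYZ, which encodes lysozyme, went from 208.65 ± 11.05 to 2433.68 ± 76.45 CPM (SD, n = 3). Genes of growth factor receptors and of proteins that signal from them rose in 14 of 17 cases, including CSF1R (3.35), MERTK (2.77) and FLT3 (1.19). Autophagy and lysosome genes rose in 24 of 30 cases, among them GABARAPL1 (2.63) and SQSTM1 (1.08), with an adjusted p of 0.115 with an estimated correlation. Interferon genes fell in 22 of 29 cases, with MX1 at -3.98, IFI44L at -4.18 and OAS2 at -2.62, while STAT2 rose by 1.69. The largest rises also included SCARA5 (6.39), CNR2 (5.78), H2AC6 (5.05), OLFML3 (5.01), ADAM28 (4.67), GUCY2D (4.59) and FGD2 (4.52), and the largest falls C3orf52 (-6.84) and GPR84 (-5.87). PSMB3 (-3.96) also met the rule, but its counts swung from 45 to 902 among the DMSO libraries, and it was at -1.58 and not called without DMSO replicate 3 (adjusted p = 0.169). With limma-voom it was at -2.81 and not called either (0.16).

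Genes of mitochondrial shape were mostly lower with ERKi. DNM1L, which encodes Drp1, on chromosome 12 (32679301 to 32745650, GRCh38), went from 136.65 ± 8.41 to 89.61 ± 1.87 CPM (SD, n = 3), a log2 fold change of -0.61 (SE 0.052, adjusted p = 1.63e-08). Of 13 fission genes 8 fell and 3 rose, with MTFP1 at -2.08 and FIS1 at -0.64, and the list did not pass (adjusted p = 0.159). Of 12 fusion genes 10 fell, with MFN2 at -0.65 and OPA1 at -0.41 (adjusted p = 0.00219, and 0.0289 with an estimated correlation). All 13 mitochondrially encoded mRNAs were higher, by 0.35 to 1.16 with a median of 0.57, such as ND3 (1.16) and COX1 (0.7), and 43 of 51 nuclear-encoded respiratory chain genes were lower, such as NDUFA9 (-0.97). With an estimated correlation these lists had adjusted p of 0.354 and 0.251.

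Of 9 BCL2 family death genes, 4 rose with ERKi, among them BMF (3.12), BBC3 (0.89) and BCL2L11 (0.61), and 4 fell, among them PMAIP1 (-1.46) and BAX (-0.26, and -0.17 without DMSO replicate 1), while BCL2 itself, the target of venetoclax, fell by 0.46. MCL1, a survival gene, was at -0.11 and lost its call without DMSO replicate 2 (adjusted p = 0.113) or 3 (0.0703) or ERKi replicate 1 (0.0579) or 2 (0.0783). Of the 6 survival genes 1 rose and 5 fell, and their log2 fold changes ran from -4.11 to 5. Neither the survival list (adjusted p = 0.799) nor the death list (0.159) passed. Of 25 p53 targets 13 rose and 7 fell, with TP53INP1 at 2.38 and CDKN1A at 0.83, and the list did not pass (adjusted p = 0.105).

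**Figure D2:**
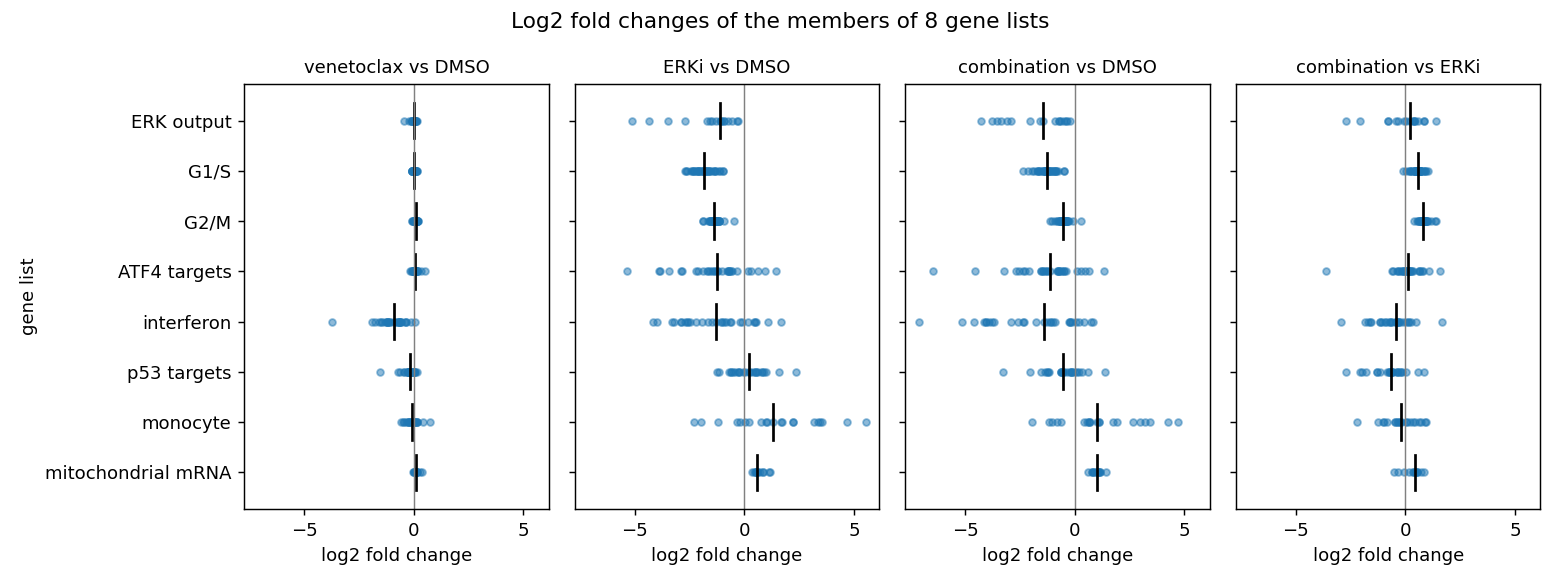
Each point is the log2 fold change of 1 gene of the list named on the vertical axis, in the comparison above the panel, and black bars are list medians. Interferon genes lie to the left with venetoclax alone (median -0.91), and G2/M genes lie to the left with ERKi (-1.37) and to the right in the combination against ERKi (0.83).

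The combination against DMSO asked for the effect of both drugs together and gave 4607 genes higher and 5068 lower. All 17 ERK output genes fell (adjusted p = 4.47e-09, and 0.00107 with an estimated correlation), with ETV4 at -4.28, DUSP6 at -3.53, CCND1 at -3.1 and EGR1 at -2.93. All 37 G1/S genes fell with a median of -1.29 (CDC6 -1.93, MCM4 -1.29) and 32 of 34 G2/M genes with a median of -0.53 (CCNA2 -1.11, CDK1 -1.03). ATF4 targets fell in 25 of 31 cases (PSAT1 -3.23, SLC7A5 -2.34) and interferon genes in 23 of 29 (24 adjusted over the list alone), with IFI44L at -7.1, MX1 at -4.61 and IFIT1 at -4.14. Monocyte genes rose in 14 of 21 cases, with LYZ at 4.26, S100A8 at 3.45, VCAN at 3.22 and CSF1R at 2.97.

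CDH6, a cadherin, had the largest rise of the combination under the rule, from 0.27 ± 0.22 to 34.64 ± 2.1 CPM (SD, n = 3), a log2 fold change of 6.97 (SE 0.262, adjusted p = 1.15e-12). OLFML3 (5.15), LTK (4.24), the prolactin receptor PRLR (3.96), FGD2 (3.91), GUCY2D (3.76) and the pyruvate dehydrogenase kinase PDK4 (3.76) followed, and GPR84 (-6.35), C3orf52 (-5.91), SYT2 (-4.57) and COL1A2 (-4.09) were among the largest falls. COL1A2 held 121 counts in DMSO replicate 1 and 406 and 287 in the other DMSO libraries. CDKN1A (-1.23), SESN2 (-1.29), MDM2 (-0.61) and FAS (-1.54) were among 15 of 25 p53 targets that fell (16 adjusted over the list alone), and the list itself had an adjusted p of 0.0564, which became 0.13 with an estimated correlation, 0.0539 with RLE factors and 0.0462 with the replicate number as a block. All 13 mitochondrially encoded mRNAs rose with a median of 1.02 (COX3 1.44, ND4 1.17), and 31 of 35 cytosolic ribosomal protein genes rose (RPS28 0.91, RPL37 0.63), with adjusted p of 0.13 and 0.232 with an estimated correlation. DNM1L was at -0.66, MFN2 at -0.25 and OPA1 at -0.36. BMF rose by 1.82, PMAIP1 fell by 1.57, BCL2 fell by 0.31, and BCL2L11 did not pass (-0.06, adjusted p = 0.326). Of the 6 survival genes 1 rose and 3 fell, and their log2 fold changes ran from -3.96 to 3.56.

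**Figure D3:**
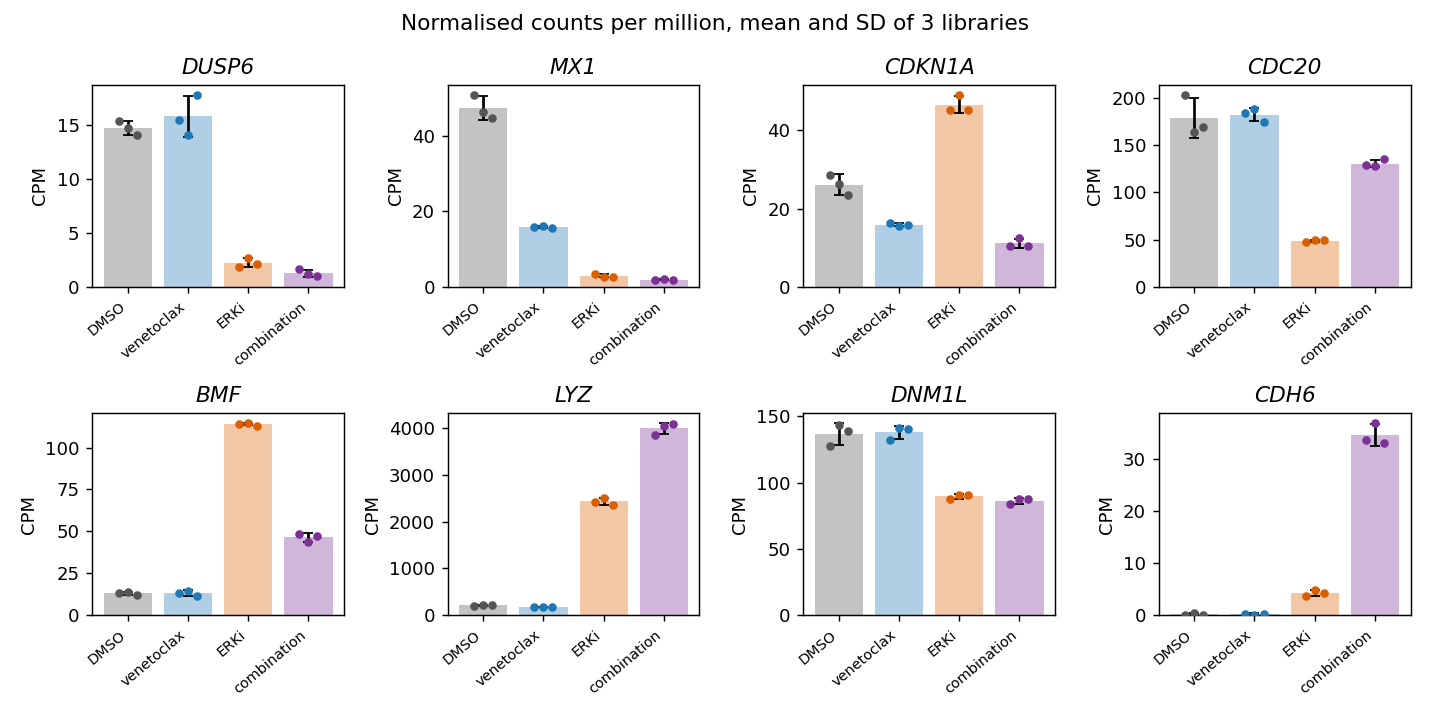
Bars are the mean CPM of 3 libraries per group, error bars the SD and points the libraries, each panel with its own linear axis from 0. CDKN1A and BMF are highest with ERKi (46.58 and 113.96 CPM) and lower in the combination (11.14 and 46.38), and DNM1L is at 89.61 with ERKi and 86.27 in the combination.

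The combination against venetoclax asked what ERKi adds to venetoclax and gave 4864 genes higher and 5183 lower. All 17 ERK output genes fell and all 37 G1/S genes fell, with ETV4 at -4.36. CDH6 (7.28), OLFML3 (5.56), FGD2 (4.81), LTK (4.75) and LYZ (4.5) led the rises, and STC2 (-6.6), GPR84 (-6.39), C3orf52 (-5.98) and SYT2 (-4.69) the falls. DNM1L was at -0.68. Interferon genes fell in 17 of 29 cases, with MX1 at -3.03 and OAS2 at -2.5, and the list had an adjusted p of 0.085 with an estimated correlation. The effect of ERKi without venetoclax and its effect on top of venetoclax, which share no library, correlated across the 15173 genes with a Pearson r of 0.742 and a Spearman rho of 0.761, where genes are not independent replicates. Of the 10578 genes called with ERKi alone, 86.661% had the same sign.

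The combination against ERKi asked what venetoclax adds to ERKi and gave 4023 genes higher and 3694 lower, of which 324 and 636 changed at least 2-fold. Proliferation genes were higher than with ERKi alone: all 34 G2/M genes (median 0.83, adjusted p = 3.94e-51, and 5.46e-05 with an estimated correlation) and 35 of 37 G1/S genes (median 0.57). CDC20, an activator of mitotic exit, was at 1.42 (SE 0.07), KIF20A at 0.97, CCNB1 at 0.84, MCM2 at 0.91 and MCM4 at 0.66. Ribosome biogenesis genes were higher in 28 of 30 cases (NOLC1 0.59). Among ATF4 targets 13 of 31 were higher and 6 lower, with PHGDH at 1.57 and SLC7A5 at 1.08, and the list did not pass (adjusted p = 0.0632).

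p53 targets were lower than with ERKi alone in 19 of 25 cases (21 adjusted over the list alone, median -0.66, adjusted p = 5.26e-11, and 0.00136 with an estimated correlation). CDKN1A, on chromosome 6 (36676463 to 36687332, GRCh38), was at 46.58 ± 2.22 CPM with ERKi and 11.14 ± 1.15 in the combination (SD, n = 3), a log2 fold change of -2.07 (SE 0.086, adjusted p = 5.17e-11), TP53INP1 was at -1.78 and MDM2 at -0.85. Of 9 death genes 3 were lower, BMF (-1.3), BCL2L11 (-0.67) and BBC3 (-0.56), and 2 higher, and the list did not pass (adjusted p = 0.0754, and 0.25 with an estimated correlation). Genes of growth factor receptors and of proteins that signal from them were lower in 9 of 17 cases (MERTK -1.69) and interferon genes in 16 of 29 (OAS1 -1.71, STAT2 -0.87). Of 21 monocyte genes 10 were lower, such as CD86 (-2.21) and CD36 (-1.03), and 4 higher (5 adjusted over the list alone), such as LYZ (0.71) and IRF8 (0.6), with a list adjusted p of 0.0279 that became 0.247 with an estimated correlation. IL1B, the cytokine gene, was at -1.65. ERK output genes also split, 9 higher and 5 lower, with EGR1 at 1.39, ETV5 at 0.84, MYC at 0.57, DUSP6 at -0.81 and PHLDA1 at -2.07 (list median 0.21, mean -0.1, adjusted p = 0.637). DNM1L did not differ past the threshold (-0.05, SE 0.052, adjusted p = 0.405), while MFN2 was at 0.4 and FIS1 at 0.46.

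Under the rule, CDH6 (3) was among the rises, and COL1A2 (-3.74), GJA1 (-3.34), the growth hormone receptor GHR (-2.45) and CACNB4 (-2.41) among the falls. COL1A2 held 170, 164 and 316 counts with ERKi and 12, 18 and 13 in the combination. Its fall is uncertain, since RNA of other cells may be missing from the combination libraries, as set out below. GSDMD (3.67), RNH1 (2.74) and EEF1D (2.42) met the rule too, with standard errors of 0.709 or more. EEF1D was at 0.33 without combination replicate 1 (adjusted p = 0.526) and at 1.51 with limma-voom (0.131), and RNH1 at 2.22 without combination replicate 1 (0.0524), none of them called.

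The interaction asked whether venetoclax acted differently with ERKi present and was called for 3227 genes above and 2724 below the sum of both single effects. All 34 G2/M, 33 of 37 G1/S and 28 of 30 ribosome biogenesis genes lay above it, and 14 of 25 p53 targets below (15 adjusted over the list alone), with adjusted p of 0.000148, 0.0018, 0.0173 and 0.0126 with an estimated correlation. DNM1L showed none past the threshold (-0.07, SE 0.073, adjusted p = 0.499). The effect of venetoclax without ERKi and its effect on top of ERKi, which share no library, correlated across the 15173 genes with a Pearson r of 0.009 and a Spearman rho of -0.059. Nearly all of these genes were not called with venetoclax alone, so a correlation near 0 does not show that the effects were unrelated. Over the 61 genes called with venetoclax alone the Pearson r was 0.476, and 43 had the same sign on top of ERKi, with 37 called there with the same sign and 9 with the opposite.

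Mitochondrial RNA took a growing share of the libraries. Mitochondrial mRNA made up 3% ± 0.23 of counts with DMSO, 3.13% ± 0.096 with venetoclax, 4.77% ± 0.32 with ERKi and 6.2% ± 0.65 in the combination (SD, n = 3), and mitochondrial rRNA 0.88% ± 0.01, 0.924% ± 0.0061, 1.41% ± 0.11 and 3.28% ± 0.075. The exact two-sided permutation p against DMSO was 0.4 for mRNA with venetoclax and 0.1, the smallest that 3 against 3 allow, for the others. The top 10 genes held 5.92% of counts with DMSO and 10.7% in the combination.

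**Figure D4:**
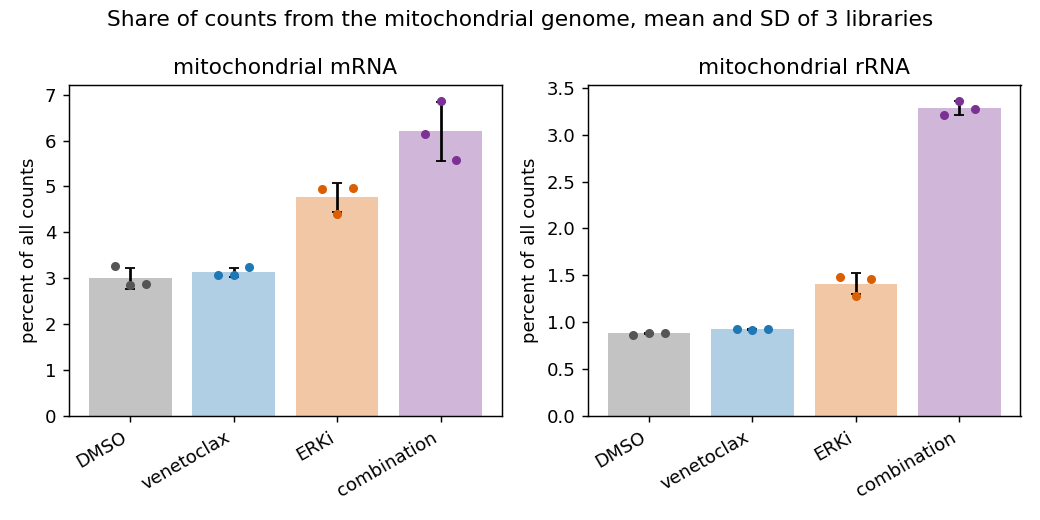
Bars are the mean percent of all counts from mitochondrial mRNA (left) and rRNA (right) in 3 libraries per group, error bars the SD and points the libraries, on axes from 0. The rRNA share is 0.88% with DMSO and 3.28% in the combination.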

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

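The tests of swinging counts in neighbouring genes, of their highest values, of RNA of other cells, of mitochondrial RNA, of ERK output, of scaling and of other splits of the samples were chosen or worded after the result was seen. The rule for samples far from their group was not applied, since groups of 3 are too small for it.

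The effect of venetoclax differed without and with ERKi, by the interaction test, for 3227 genes that lay above and 2724 below the sum of both effects. Of 31 lists 10 lay above that sum and 4 below. Above it were G2/M (adjusted p = 3.88e-40), G1/S (6.09e-19), ribosome biogenesis (1.88e-17), cytosolic ribosomal protein (0.000146), glycolysis (0.000404), nuclear-encoded respiratory chain (0.000407), granulocyte (0.00721), interferon (0.0268), tricarboxylic acid cycle (0.0375) and unfolded protein response genes (0.0408). Below it were p53 targets (6.69e-06), growth factor receptors with the proteins that signal from them (0.0192), autophagy and lysosome genes (0.0408) and inflammatory genes of the NF-kB list (0.0421). With an estimated correlation G2/M, G1/S, ribosome biogenesis and p53 targets passed, and the others had an adjusted p of 0.0946 to 0.477. On the log2 scale the interaction was 1.39 for CDC20, 1.31 for PLK1, 0.91 for MCM2, 1.66 for PHGDH, 0.67 for MYC, 1.39 for EGR1 and 0.42 for MFN2. It was 1.17 for CMPK2, an interferon gene. It was -1.35 for CDKN1A, -0.71 for MDM2, -1.3 for BMF, -0.56 for BCL2L11, -0.58 for BBC3 and -0.91 for DUSP6. Under the rule of size it was 3.31 for CDH6, -5.88 for THBS1, -3.78 for STC2 and -3.28 for COL1A2. THBS1 held 8 counts in DMSO replicate 1 and 102 and 113 in the other DMSO libraries. SCAMP3 (5.13), AATF (3.93), VARS1 (3.08), EEF1D (3.07) and FRG1 (-2.93) had standard errors of 0.862 or more. AATF was at 2.44 without DMSO replicate 3, still called (adjusted p = 0.00186). With limma-voom SCAMP3 (4.25), VARS1 (2.04), EEF1D (2.15) and FRG1 (-1.87) were not called (adjusted p = 0.24, 0.201, 0.155 and 0.163), nor were FRG1 with DESeq2 (0.0665) and EEF1D with the replicate block (0.0501). SCAMP3 also lost its call without DMSO replicate 2 (0.0599), venetoclax replicate 3 (0.0505), ERKi replicate 1 (0.0503) or combination replicate 2 (0.273), where it was at 2.69, and was at 8.04 without ERKi replicate 2. VARS1 did so without DMSO replicate 3 (0.104), venetoclax replicate 1 (0.0566), ERKi replicate 2 (0.0571) or 3 (0.0535) or combination replicate 1 (0.193), and was at 1.75 without the first and 1.64 without the last. EEF1D did so without DMSO replicate 2 (0.0633), venetoclax replicate 1 (0.0612), ERKi replicate 3 (0.0526) or combination replicate 1 (0.159), where it was at 0.97. FRG1 did so without venetoclax replicate 2 (0.518), where it was at -0.48, ERKi replicate 3 (0.0561) or combination replicate 3 (0.0632).

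For the interaction, 1 of 100 groupings of the 12 libraries, the real one, gave as many called genes: 5951, with 5921 as the highest of the others. That margin is small. These draws moved libraries between all 4 groups, so the effects of single drugs could enter the contrast. They are not a clean measure of chance for an interaction, so neither the share nor the margin decides it. Of the 99 other draws 90 called 0 genes. In 17 draws the ERKi libraries all had the same sign in the contrast, which carries the ERKi effect into it, and 12 of these called 0 genes and 5 called 334 to 5921, while the other 82 draws called 0 to 1790. The draw with 1790 had all venetoclax libraries of the same sign and all combination libraries of the opposite sign. Another draw with the same balance of signs in each group called 2. Why only some of these draws called many genes was not tested. For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05. Fitted to those 6 libraries alone, the real split (1 of 10 in each case) called 33 genes for venetoclax against DMSO with 3 as the highest other, 9960 for ERKi against DMSO with 0, 8872 for the combination against DMSO with 0, 10291 for the combination against venetoclax with 0, and 8373 for the combination against ERKi with 1.

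Proliferation genes were higher in the combination than with ERKi alone. Weaker ERK inhibition in the combination would by itself leave ERK output genes level or higher. Of 17, 9 were called higher, EGR1, ETV5 and MYC among them, and 5 lower. The 5 were DUSP4, DUSP6, LIF, MAFF and PHLDA1, of which DUSP4, LIF and MAFF were named after their values were seen. These 5 could have fallen for another reason, so the split cannot decide, and weaker inhibition stays open. The scaling of libraries rich in mitochondrial RNA would move all genes alike. Yet the median of the G2/M genes lay 0.83 above that of all tested genes on the log2 scale, with 34 of 34 above it. This argues against scaling as the cause of their rise relative to other genes. A factor per library drops out of that difference, so it cannot show whether G2/M RNA rose or the other RNA fell. A response of the cells to venetoclax, or a loss of arrested cells from the combination, may underlie the pattern, and neither was tested. DMSO replicate 1 and the combination shared low counts of 19 genes, as set out below. On the second principal component DMSO replicate 1 was at 10.5, the other DMSO libraries at -9.5 and -6.6, and the combination at 34.5 to 36.5. A difference in handling of the combination libraries thus cannot be told apart from the drugs, in each comparison with the combination and in the interaction.

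The share of mitochondrial mRNA rose with ERKi and further in the combination. A smaller pool of nuclear-encoded mRNA would move all 13 by the same factor, yet with ERKi their log2 fold changes, from COX2 as the lowest to ND3 as the highest, spread more widely than their standard errors allow (variance ratio 6.69 over all 13), which argues against it as the whole cause. Carry-over of RNA without poly(A) tails cannot be told apart from a change in the cells: nuclear RNA without tails other than histone RNA was 2.38 times its DMSO level with ERKi and 12.28 times in the combination, and replication histone RNA 5.9 and 2.5 times, but the former ran from 24.5 to 79.9 counts in 1e+06 with ERKi and from 17.1 to 23.8 with DMSO. From ERKi to the combination these signs moved apart, with nuclear RNA without tails other than histone RNA at 5.16 times, mitochondrial rRNA at 2.33 times and histone RNA at 0.42 times, where 6 of 16 histone genes were called higher and 4 lower. The median of these histone genes was 0.11 on the log2 scale, so their summed share does not describe most of them. Effects of the drugs on mitochondria stay open and were not tested.

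Some genes swung between libraries of the same group: 68 of 15173 differed at least 4-fold within at least 2 groups, with at least 50 counts in the highest library of each. A single library as the whole cause was argued against, since at most 48.5% of the 68 had their lowest and 47.1% their highest value in the same library of a group. Of the 65 with a position, 16 had another such gene as nearest tested neighbour, against a median of 0 and at most 8 in 10000 random draws, which is consistent with reads placed on alternate copies of a locus for some of these, while 49 had none. RNA of other cells may account for others: 10 genes, among them KRT13, C3 and CLU of the 68, were at least 2 times higher in replicate 2 of DMSO, venetoclax and ERKi than in the other libraries of these groups (at most 1 gene for the 26 other choices of libraries), and 19, among them COL1A1 of the 68 and THBS1, were at least 2 times lower in DMSO replicate 1 and the combination than in the other 8 (at most 3 with another library in its place), where KRT13, C3, CLU and COL1A1 were named after their values were seen. No biological explanation was tested, and the fold changes of SCAMP3, VARS1, GSDMD, RNH1, PSMB3, THBS1 and COL1A2 are uncertain, as are those of EEF1D and FRG1, which rest on 1 library. The size of the AATF interaction is uncertain too, since it went from 3.93 to 2.44 without DMSO replicate 3.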

How the results depend on the processing

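The scaling without mitochondrial and non-polyadenylated RNAs, the counts without genes of swinging counts and the list counts without DMSO replicate 1 were chosen after seeing the data. Scaling by RLE factors or without those RNAs moved the median of all genes by 0.017 or less. These scalings, like the main one, take most genes as unchanged, so their agreement cannot test that assumption. Most genes were in fact called for ERKi against DMSO (69.7%) and for the combination against DMSO (63.8%), venetoclax (66.2%) and ERKi (50.9%). Directions in these comparisons therefore rest on rises and falls balancing each other. Of the 12 counts of called genes, the 10 other than those of venetoclax against DMSO stayed within 1.5 times under each setting. For venetoclax against DMSO, the 3 higher genes became 12 with DESeq2, 74 with no filter, 1 with only the libraries compared, 1 with the scaling without mitochondrial and non-polyadenylated RNAs, and 1 to 17 with single libraries left out. The 58 lower genes became 168 with no filter, 32 with only the libraries compared, and 30 to 81 with single libraries left out. The cause was not tested. Deviations of same-numbered libraries correlated between -0.074 and 0.094 over 18 pairs, and of others between -0.091 and 0.066, though replicate 2 of 3 groups shared 10 genes of high counts. With the replicate block, 1 gene was higher and 47 lower with venetoclax. The Pearson r of the ERKi effect without and with venetoclax (0.742) became 0.822 over genes of mean CPM at least 5 and 0.7 to 0.753 with single libraries left out, and that of the venetoclax effect without and with ERKi (0.009) became -0.024 and -0.119 to 0.098.

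Of the named genes, 11 pairs of gene and comparison changed sign, and in these the values lay near 0 and no sign change was called. EGR1 with venetoclax was at 0.01 with RLE factors and DESeq2 and at 0 with limma-voom and the replicate block. BAX in the combination against ERKi was at -0.01 with the filter of CPM 1 in 3 libraries, 0 with only the libraries compared and -0.01 with the scaling without mitochondrial and non-polyadenylated RNAs. With single libraries left out, values with venetoclax ran from -0.09 to 0.07 for EGR1, -0.13 to 0.11 for MAPK3, -0.04 to 0.05 for DNM1L, -0.16 to 0.1 for FIS1, -0.01 to 0.08 for MFF, -0.05 to 0.02 for MFN2, -0.02 to 0.12 for BCL2 and -0.05 to 0.09 for BBC3. In the combination against DMSO they ran from -0.18 to 0.07 for MAPK3 and -0.09 to 0.04 for MFN1, and against ERKi from -0.04 to 0.04 for BAX. The cause was not tested. Over all named genes and settings, direction and side of the threshold were the same in 3846 values, while 118 lost and 4 gained their call and 28 changed sign. Of the list tests 344 stayed on their side, 36 lost and 20 gained their call, 19 of the 20 with fry, which asks whether members moved at all.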

Other observations

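Some further lists gave mixed or less certain results. In the combination against DMSO, 9 of 12 granulocyte genes rose, among them CSF3R (1.7) and CTSG (1.36), with an adjusted p of 0.00137 that became 0.0808 with an estimated correlation, and MMP9 was at -4.44. With ERKi alone 6 rose and 4 fell, and the granulocyte list did not pass (adjusted p = 0.206). Replication histone genes were higher in 13 of 16 cases in the combination against DMSO (adjusted p = 0.0201, and 0.238 with an estimated correlation). Fatty acid oxidation genes went both ways, 7 higher and 9 lower, with a median of -0.04, a mean of 0.18 and the carnitine transferase CPT1A at 1.68. Inflammatory genes of the NF-kB list did not pass as a list (adjusted p = 0.172), with IL1B at -2.33 and TNFAIP3 at -2.56.

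Few markers of other lineages were measured: 5 erythroid and megakaryocyte and 4 lymphoid genes. Neither list passed with ERKi (adjusted p = 0.45 and 0.918) or in the combination against DMSO (0.481 and 0.82), and the lymphoid medians and means differed in sign (-0.11 and 0.08 with ERKi, 0.7 and -0.17 in the combination). NFE2, an erythroid and megakaryocytic factor, was at 3.16 with ERKi and 2.12 in the combination, and the transferrin receptor TFRC at -2.19 and -1.86.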
